A study of Mus musculus with 12 samples.

How the data were processed

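RNA from cardiomyocytes of male mice was measured in 12 libraries. Per the labels, RNA was isolated with a Maxwell RSC simplyRNA kit and libraries were made with the SMART-Seq Stranded kit, which keeps the strand of the transcript. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7a and HTSeq 0.13.5 were used, with the mouse genome build GRCm38 (mm10). Each deposited file holds whole-number counts of reads per gene, as the authors' HTSeq step left them, with no normalization. Each file lists 55335 gene identifiers. Symbols, positions and strands came from the mouse annotation supplied for GRCm38, which matched 55154 of them and left 181 without a symbol.

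Libraries were grouped by genotype and diet as the labels give them, with 3 replicates in each of 4 groups. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries. Replicates of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of 24.5 to 189.7 over genes with at least 20 counts among the 11 libraries used, so none was counted as a duplicate. The groups share replicate numbers. Of 15 pairs of libraries with the same number in different groups, 3 had deviations from their group means that correlated above 0.1, with a range of −0.412 to 0.319, and the labels name no shared litter, batch or day, so the libraries were not treated as paired.

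The 12 totals ranged from 1347110 to 46424614 counts. The file of WT_HFD replicate 3 held counts of the opposite strand and was left out of the reported comparisons before any call was seen. The design fixed beforehand had all 12 libraries in the fit. The fit of 11 libraries was one of the alternatives planned beforehand. With a group of 2 libraries, WT_HFD has less weight in every comparison it enters.

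Differences were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited: TMM scaling factors, filterByExpr by group at its defaults, 1 mean per group, and the robust quasi-likelihood F test. This kept 16932 genes, with 7 residual degrees of freedom and a common biological coefficient of variation of 0.2. P-values are two-sided and adjusted by the Benjamini-Hochberg method within each of 6 comparisons: 5 between pairs of groups and the interaction of diet with genotype. A gene was called at an adjusted p under 0.05. Standard errors are those of the fitted log2 fold changes. Group values are means of TMM-scaled CPM (counts divided by the library total, in the usual unit) with their SD, except that Apoe is also given as plain CPM.

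Before the data were examined, 28 gene lists were fixed: fatty acid oxidation enzymes, PPAR-alpha targets, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, LXR targets, interferon-stimulated genes, NF-kappaB and cytokine genes, antigen presentation, hypertrophy and fetal genes, sarcomere and calcium handling, extracellular matrix, unfolded protein response, oxidative stress, heat shock, immediate early genes, clock genes, cell cycle genes, and markers of endothelium, fibroblasts, macrophages, lymphocytes and neutrophils, pericytes and smooth muscle, erythroid cells and platelets, adipocytes, atrial cardiomyocytes, and neural cells. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated per list, and fry, stand beside it. Member counts are given over all genes tested and adjusted over the list alone.

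The rule for named genes was also fixed beforehand. In each comparison it takes Apoe, then up to 10 higher and 10 lower called genes with the largest changes that had a mean log2 CPM of at least 3 and no overlap between the 2 groups, leaving out predicted genes, pseudogenes and genes with no symbol. It then takes up to 4 called members of each list, or 2 members as values where a list passed and no member did. Where fewer than 5 genes passed, the smallest p-values fill up to 5. Some genes that the rule takes are not reported. Genes named outside the rule are said to be chosen after their values were seen.

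The region around Apoe was described by the tested genes within 10 Mb, with windows of 5 and 20 Mb as alternatives, and compared with all other tested genes by Fisher's exact test. Overlaps between comparisons were set against the product of the 2 counts divided by the genes tested. Strand was checked on pairs made of a protein-coding gene and a non-coding gene that overlaps it on the other strand. Shares of single libraries carry 95% Wilson intervals, which cover counting error only.

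Alternatives were RLE factors, DESeq2 1.42.0, no filter, a filter of 50 counts in 3 libraries, only the 2 groups compared, the replicate number as a block, voom with sample weights, a covariate of non-myocyte markers, and each library left out in turn. The fit of all 12 libraries is the one the design fixed beforehand, and stands among the alternatives because 11 libraries are reported. Added after seeing the data were the removal of mitochondrial genes, a covariate of clock genes and a covariate of atrial genes. On simulated counts with 200 changed genes among 16654, the test recovered 41% of genes changed 2-fold and 69% of those changed 4-fold for ApoeKO_HFD against WT_CD. For the interaction it recovered 11% and 54%. Across the 6 comparisons 5.8% to 9.4% of the simulated calls were false, at an adjusted p threshold of 0.05. A raised list of 25 genes gave a camera p of 1.47e-20 in the simulation of ApoeKO_HFD against WT_CD, where 4 of 200 unchanged lists had p under 0.05. Simulated genes were drawn independently, so this does not show how camera treats lists whose genes vary together. Each simulated gene had the same spread in every library, while the real WT_CD libraries had the lowest voom sample weights. The simulated rates therefore do not cover that uneven spread. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.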

Results

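Cardiomyocyte RNA of male mice was sequenced in 12 libraries, which the labels put into 4 groups of 3. The groups cross genotype with diet. Mice were wild-type C57BL/6J or carried a knockout allele of Apoe, the gene of the lipoprotein component apolipoprotein E, and ate chow or a Western-type high fat diet for 7 weeks. The groups are abbreviated WT_CD, WT_HFD, ApoeKO_CD and ApoeKO_HFD. The series is about metabolic stress in mice as a model of diastolic heart failure (HFpEF). By the labels, ApoeKO_HFD against WT_CD sets the combined model against the plain control, and the other comparisons separate diet from genotype.

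In 11 libraries between 22130323 and 46424614 counts fell on genes. Transcripts of the mitochondrial genome took 51.5% to 71.3% of them, which left at least 9340449 counts on nuclear genes. WT_HFD replicate 3 held 1347110 counts in all. On 877 pairs of a protein-coding gene and a non-coding gene overlapping it on the other strand, 60.8% of its counts were on the non-coding member (95% Wilson interval 60.6% to 61.0%), against 0.18% to 0.259% in the other libraries. Its counts therefore stood on the opposite strand, and the comparisons use the 11 other libraries, with n = 2 for WT_HFD and n = 3 for each other group. The design fixed beforehand had all 12 libraries in the edgeR fit, which calls 0 genes for ApoeKO_HFD against WT_CD (576 at an unadjusted p under 0.05; 26 are called with 11 libraries) and 1 to 8 in each other comparison.

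**Figure D1:**
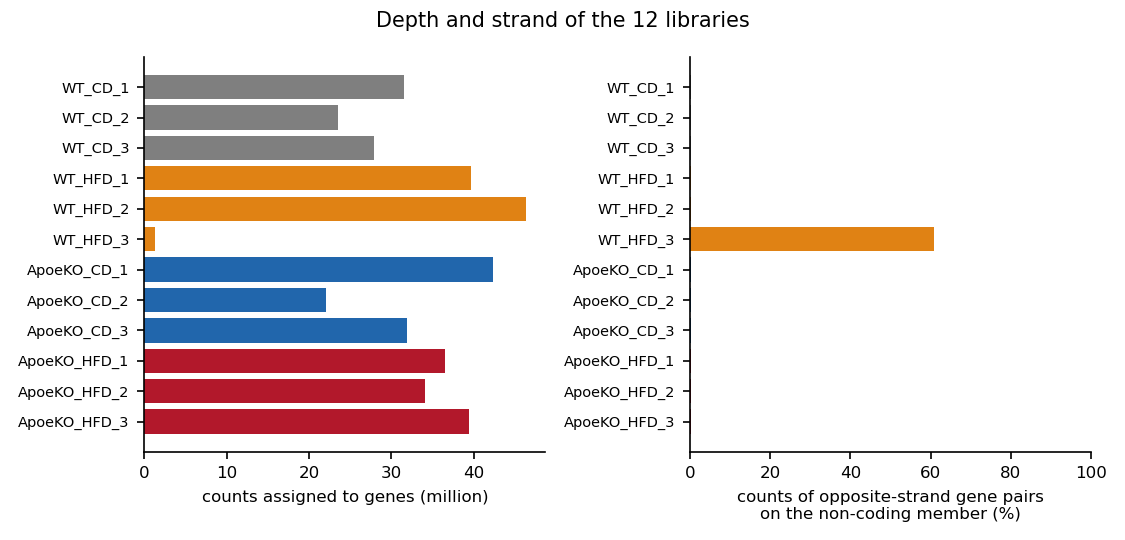
Left, counts assigned to genes in each of the 12 libraries. Right, the percentage of counts of opposite-strand gene pairs that fell on the non-coding member, where WT_HFD replicate 3 stands at 60.8% and each other library at or under 0.259%.

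Apoe, the targeted gene, went against the genotype labels on chow and with them on the high fat diet. The gene (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) had 2.88 ± 0.579 CPM (SD, n = 3) in the libraries labelled WT_CD and 19.0 ± 9.51 (n = 3) in those labelled ApoeKO_CD. On the high fat diet it had 12.8 ± 6.52 CPM (n = 2) in the libraries labelled WT_HFD and 2.59 ± 0.523 (n = 3) in those labelled ApoeKO_HFD. Every library labelled ApoeKO_CD lay above every library labelled WT_CD, with 274 to 898 counts against 54 to 96. The edgeR log2 fold change of ApoeKO_CD against WT_CD was 2.69 (SE 0.53, adjusted p = 0.0646), and that of ApoeKO_HFD against WT_HFD was −2.34 (SE 0.55, adjusted p = 0.832), so neither passed by edgeR. DESeq2 called both, in these directions. Their difference, the interaction of genotype with diet, was −5.03 (SE 0.76, adjusted p = 0.0427). That call was lost without any 1 of the WT_CD libraries, WT_HFD replicate 1 or any 1 of the ApoeKO_HFD libraries, with a range of −5.55 to −4.38. The count covers the whole gene, so transcripts of an interrupted allele are counted too. Groups are named by their labels throughout. Only if the labels of the chow groups hold is ApoeKO_HFD against WT_CD the combined model, and are the comparisons within a genotype label about diet alone. With those labels exchanged, the former would be about diet alone and the latter would mix diet with genotype. ApoeKO_CD against WT_CD would then have its sign reversed, and the interaction would be the sum of the genotype effects on the 2 diets.

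Genes near Apoe followed the same arrangement. The genes of this paragraph other than Lgals4, Bcam and Ccdc9 were chosen after their values were seen. Igsf23, an immunoglobulin superfamily gene (chromosome 7, 19937305 to 19950756), was lower in the libraries labelled ApoeKO_CD than in WT_CD, with a log2 fold change of −3.06 (SE 0.30, adjusted p = 5.56e-05). It was higher in those labelled ApoeKO_HFD than in WT_HFD, by 3.40 (SE 0.34, adjusted p = 7.53e-05). Pnmal2 changed by −1.82 (SE 0.24) on chow and 2.25 (SE 0.28) on the high fat diet. Blvrb, which encodes a biliverdin reductase, changed by −1.97 (SE 0.27) and 2.43 (SE 0.32), with adjusted p of 0.00211 or less for both genes and diets. Of the opposite kind were Bcam, a laminin receptor, at 0.73 (SE 0.12, adjusted p = 0.00859) and −0.65 (SE 0.14, adjusted p = 0.142), and Lgals4, a galectin, at 0.54 (SE 0.20, adjusted p = 0.212) and −2.46 (SE 0.23, adjusted p = 7.18e-05). Each of these passed on 1 diet only. Among 243 tested genes within 10 Mb of Apoe, 11 were called for genotype on chow (Fisher's exact test, odds ratio 10.5, 95% interval 4.96 to 20.2, p = 4.03e-08). On the high fat diet 5 were called (the same exact test, odds ratio 117, interval 22.5 to 755, p = 3.16e-08) and in the interaction 13 (odds ratio 40.9, interval 18.8 to 85.4, p = 1.37e-15), among them Ccdc9. Across these genes the log2 fold changes of the 2 genotype comparisons, which share no library, correlated at −0.52, against −0.06 across genes elsewhere. Random sets of 243 genes gave −0.25 to 0.13 (5th to 95th percentile), and genes are not independent replicates. Near Apoe, 9 of the genes called in WT_HFD against WT_CD and 8 of those called in ApoeKO_HFD against ApoeKO_CD were found, and 1 of those called in ApoeKO_HFD against WT_CD.

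**Figure D2:**
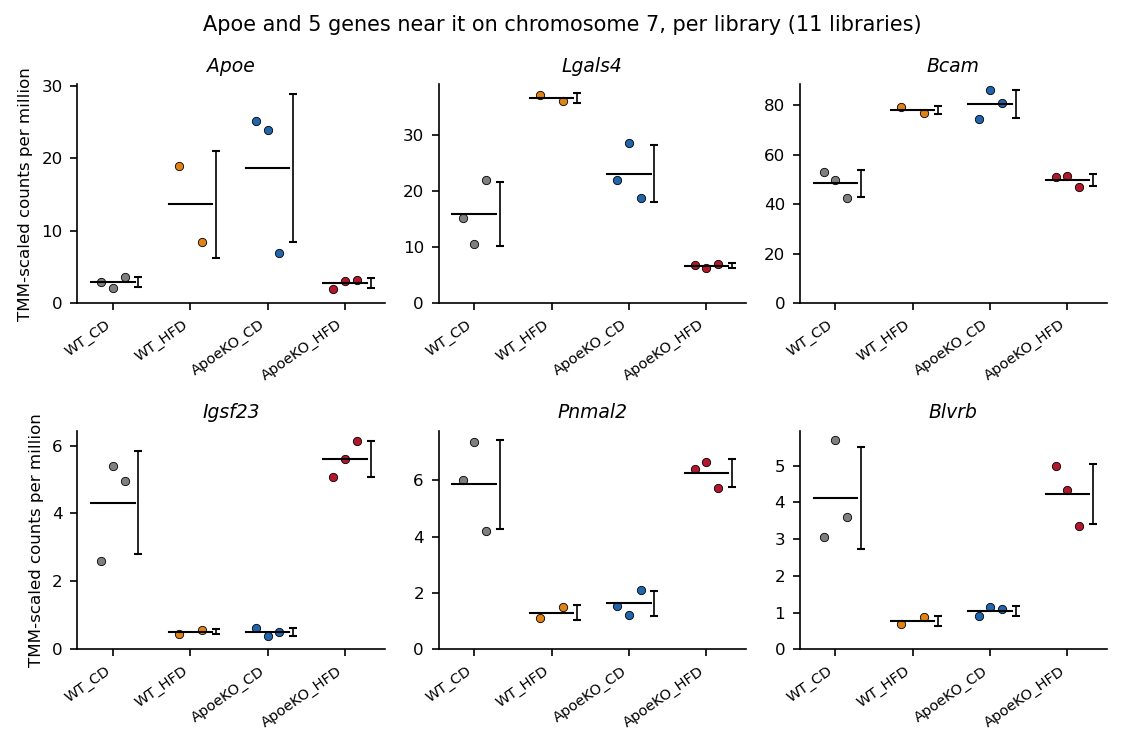
TMM-scaled CPM of Apoe and 5 genes within 10 Mb of it in each of 11 libraries by labelled group (points, libraries; line, mean; bar, SD). Igsf23, Pnmal2 and Blvrb are high in WT_CD and ApoeKO_HFD and low in the other 2 groups, and Apoe and Bcam have the opposite arrangement. Lgals4 is lowest in ApoeKO_HFD and highest in WT_HFD, and its chow groups overlap.

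**Figure D3:**
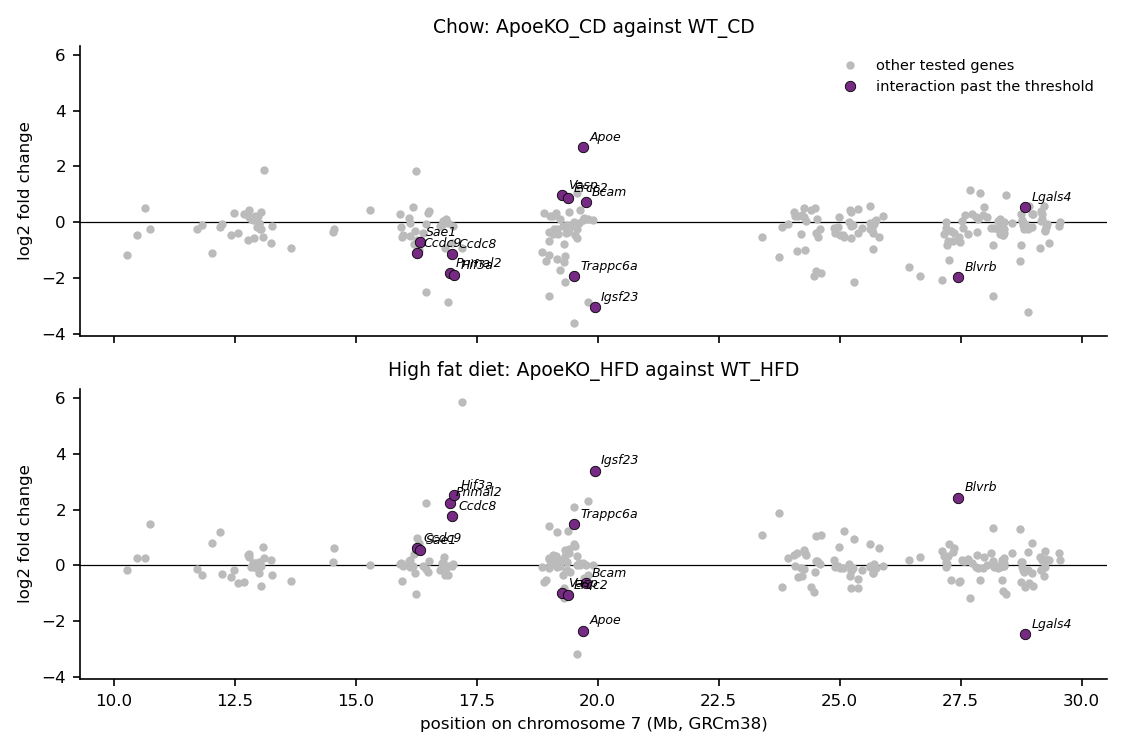
Log2 fold change of ApoeKO against WT on chow (top) and on the high fat diet (bottom) for tested genes within 10 Mb of Apoe, by position on chromosome 7 in Mb. Purple points are Apoe and other genes whose interaction passed the threshold, and each of those shown lies on opposite sides of 0 in the 2 panels.

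ApoeKO_HFD against WT_CD asks what the combined model changes. Single genes were lower, among them Atp5k, Fos, Gadd45g and Srebf1. Atp5k, a subunit of mitochondrial ATP synthase, fell 2.84-fold (SE 0.19 in log2, adjusted p = 0.00589), from 80.2 ± 27.0 CPM (SD, n = 3) to 28.3 ± 6.22 (n = 3). It stood as low in WT_HFD (28.4) and ApoeKO_CD (26.2). Mir6236, Ccdc124, Drap1 and Dusp27 were likewise high and Sord, AC132253.9 and Tmed7 low in mean in WT_CD alone, so none of these is specific to the combined model. On the log2 scale Fos, a subunit of the transcription factor AP-1, fell by 1.03 (SE 0.19, adjusted p = 0.0367). Gadd45g, a stress-induced growth arrest gene, fell by 1.35 on that scale (SE 0.23, adjusted p = 0.0343). Srebf1, which encodes the lipogenic transcription factor SREBP-1, fell by 0.97 (SE 0.19, adjusted p = 0.0495). Gadd45g and Srebf1 were also called lower in ApoeKO_CD against WT_CD. Srebf1 had 9.64 to 17.9 CPM in ApoeKO_CD and 15.5 to 16.7 in ApoeKO_HFD. Fos had 44.1 to 74.3 CPM in ApoeKO_CD, 47.9 to 50.4 in ApoeKO_HFD and 81.0 to 112 in WT_CD. These falls are therefore not shown to be specific to the combined model either. Lgals4 fell 2.38-fold. On the log2 scale the microRNA gene Mir6236 fell by 1.62, and Ccdc124, Drap1 and Dusp27 by 0.74, 0.70 and 0.67. Higher on that scale were Sord, which encodes sorbitol dehydrogenase, by 0.73 (SE 0.14), and the long non-coding RNA AC132253.9 by 0.94 (SE 0.18). Tmed7, a vesicle cargo receptor that shares sequence on the same strand with Ticam2, was higher by 0.88 (SE 0.15). In all, 5 genes were higher and 21 lower by edgeR's quasi-likelihood test, and 2410 had an unadjusted p under 0.05 where chance gives 847. With only the 2 groups fitted it was 1429. The groups share 1 estimate of the spread, and the WT_CD libraries had the lowest voom sample weights, 0.37 to 0.68 against 0.74 to 2.13 elsewhere. P-values against WT_CD may therefore be too small and those between other groups too large. None of the 26 overlapped between groups, which holds for 15.6% of all tested genes and for 10% by chance. The count was 1304 without WT_CD replicate 2, 4 without WT_CD replicate 3, 1 without ApoeKO_HFD replicate 1, and 0 without ApoeKO_HFD replicate 2 or 3. In those 2 fits, also by edgeR, 1804 and 1590 genes had an unadjusted p under 0.05. Atp5k was lost without ApoeKO_HFD replicate 2 or 3 (−1.70 to −1.20), and Fos (−1.16 to −0.93) and Srebf1 (−1.10 to −0.76) without WT_CD replicate 3 or any 1 of the ApoeKO_HFD replicates. Mir6236 (−1.84 to −1.41) and Drap1 (−0.77 to −0.61) were lost in those same 4 fits. Gadd45g (−1.40 to −1.31), Lgals4 (−1.47 to −0.95), Ccdc124 (−0.85 to −0.57), Dusp27 (−0.73 to −0.57), Sord (0.62 to 0.83), Tmed7 (0.77 to 1.06) and AC132253.9 (0.75 to 1.26) passed only without WT_CD replicate 2.

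Immediate early genes and targets of the fatty acid sensor PPAR-alpha had the smallest camera p in the same comparison, and atrial genes the largest median. Of 23 immediate early genes 22 had values below 0, with a median log2 fold change of −0.67; 1 passed over all genes, Fos, and 11 when adjusted over the list alone. Camera gave an adjusted p of 2.86e-16 (adjusted p = 0.282 with an estimated correlation). Of 22 PPAR-alpha targets 19 lay below 0, with a median of −0.41; 0 passed over all genes and 8 adjusted over the list alone (camera adjusted p = 2.54e-08; adjusted p = 0.352 with an estimated correlation). Acot1, a thioesterase, had −1.02 (SE 0.21, adjusted p = 0.0579). Atrial cardiomyocyte genes had a median of −1.34, with 13 of 13 below 0 (camera adjusted p = 0.000315; adjusted p = 0.622 with an estimated correlation). The atrial light chain gene Myl7 had 0.261 and 0.601 CPM in ApoeKO_HFD replicates 2 and 3 and 0.0668 in WT_HFD replicate 2, against 4.15 to 17.7 in the other 8 libraries. With a covariate of atrial genes the number of called genes in this comparison was 1.

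Further lists passed camera with lower values in this comparison, and none of them kept its call with an estimated correlation. Fatty acid oxidation enzymes had a median of −0.22 (24 of 25 below 0, adjusted p = 0.000698; adjusted p = 0.946 with an estimated correlation), and LXR targets, genes of cholesterol efflux and lipid synthesis, −0.45 (adjusted p = 0.00348; adjusted p = 0.33 with an estimated correlation). Antigen presentation genes had −0.42 (adjusted p = 0.00335; adjusted p = 0.622 with an estimated correlation) and endothelial markers −0.32 (adjusted p = 0.00762; adjusted p = 0.946 with an estimated correlation). Nuclear oxidative phosphorylation genes had −0.04 (adjusted p = 0.0196), macrophage markers −0.58 (adjusted p = 0.047) and hypertrophy and fetal genes −0.19 (adjusted p = 0.047), each with adjusted p = 0.946 with an estimated correlation. Without the atrial genes Nppa, Myl4 and Myl7, a removal chosen after the values were seen, the hypertrophy list had an unadjusted p of 0.0779. Myl7 had 0.261 and 0.601 CPM in ApoeKO_HFD replicates 2 and 3 and 4.57 in replicate 1. Without WT_CD replicate 2 the calls on fatty acid oxidation (adjusted p = 0.557), oxidative phosphorylation (0.557), LXR targets (0.0777) and hypertrophy (0.258) were lost. Without WT_CD replicate 1 those on antigen presentation (0.0633), hypertrophy (0.171), endothelial (0.357) and macrophage genes (0.436) were lost, and without WT_CD replicate 3 that on endothelial markers (0.619). Leaving out ApoeKO_HFD replicate 1 ended the calls on endothelial (0.0569) and macrophage markers (0.14), replicate 2 those on oxidative phosphorylation (0.266), hypertrophy (0.355) and macrophage markers (0.188), and replicate 3 those on oxidative phosphorylation (0.957) and hypertrophy (0.176). Without 1 library the medians ran from −0.39 to 0.02 for fatty acid oxidation, −0.26 to 0.19 for oxidative phosphorylation, −0.45 to −0.13 for hypertrophy, −0.62 to −0.11 for endothelial and −0.85 to −0.14 for macrophage markers.

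The other lists did not pass in this comparison. Camera's adjusted p was 0.885 for glycolysis, 0.273 for mitochondrially encoded genes, 0.64 for cholesterol synthesis, 0.103 for interferon-stimulated genes, 0.337 for NF-kappaB and cytokine genes and 0.858 for sarcomere and calcium handling genes. It was 0.672 for extracellular matrix genes, 0.579 for the unfolded protein response, 0.885 for oxidative stress, 0.292 for heat shock, 0.592 for clock genes and 0.879 for cell cycle genes. Among markers it was 0.32 for fibroblasts, 0.885 for pericytes and smooth muscle, 0.454 for erythroid cells and platelets, 0.885 for adipocytes and 0.885 for neural cells. Lymphocyte and neutrophil markers had 4 tested members and were not tested as a list. Their values included Csf3r at −1.32 (SE 0.87; −1.81 to −0.62 without 1 library) and Cd3e at −1.16 (SE 0.94; −1.84 to −0.78). Metallothionein Mt2 had 1.81 (SE 0.48, adjusted p = 0.139) and the glucose transporter gene Slc2a1 0.90 (SE 0.23, adjusted p = 0.112).

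ApoeKO_HFD against ApoeKO_CD gives the effect of diet under the knockout label. Scd2, a stearoyl-CoA desaturase (ENSMUSG00000025203, chromosome 19), rose by 1.73 on the log2 scale (SE 0.23, adjusted p = 0.00199), from 2.56 ± 0.234 CPM (SD, n = 3) to 8.56 ± 1.91 (n = 3). Zkscan3, a zinc finger gene, rose by 0.93 (SE 0.17, adjusted p = 0.0382). Lgals4 fell by 1.79 (SE 0.21, adjusted p = 0.000983) and Bcam by 0.69 (SE 0.12, adjusted p = 0.0382). LXR targets were higher as a list by camera: 11 of 13 lay above 0, with a median of 0.36, 1 called over all genes and 3 adjusted over the list alone. Camera gave an adjusted p of 5.91e-12 (adjusted p = 0.0146 with an estimated correlation), and fry, which tests the list in 1 direction without comparing it with other genes, 0.0702. Of the 12 called genes, 9 were higher and 3 lower, none overlapped between groups, and 8 lay near Apoe. An unadjusted p under 0.05 was found for 259 genes where chance gives 847, and for 556 with only the 2 groups fitted. The count was 7 without ApoeKO_CD replicate 1 or ApoeKO_HFD replicate 3 and 6 without ApoeKO_CD replicate 2 or ApoeKO_HFD replicate 2. Scd2 and Lgals4 passed in each of the 6 fits that left out 1 library, Zkscan3 in 1 (0.75 to 1.13) and Bcam in 0 (−0.74 to −0.64).

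Macrophage, hypertrophy and atrial genes were lower in the same comparison. Of 20 macrophage markers 19 lay below 0, with a median of −1.05 (camera adjusted p = 1.69e-09; adjusted p = 0.362 with an estimated correlation; −1.50 to −0.69 without 1 library). The fall was not shared by every ApoeKO_CD replicate: Lyz2, a macrophage gene chosen after its values were seen, had 8.94, 8.59 and 1.14 CPM in ApoeKO_CD replicates 1 to 3 and 2.20, 2.02 and 2.76 in ApoeKO_HFD. Csf1r and C1qb, also chosen so, had 0.961 and 0.202 CPM in ApoeKO_CD replicate 3, below each ApoeKO_HFD library. Adgre1, a macrophage surface receptor, had −1.43 (SE 0.54) and the scavenger receptor gene Cd163 −1.37 (SE 0.55), each with an adjusted p of 1. Hypertrophy and fetal genes had a median of −0.45, with 19 of 21 below 0 (adjusted p = 2.06e-09; adjusted p = 0.238 with an estimated correlation). That median was −0.13 without ApoeKO_CD replicate 3 and −0.79 without ApoeKO_HFD replicate 1. Among them, Myh7, the slow myosin heavy chain, had −1.30 (SE 0.42) and Ccn2, a matricellular growth factor, −0.72 (SE 0.24), with adjusted p of 1. Atrial genes had −1.22 (adjusted p = 4.8e-07; adjusted p = 0.326 with an estimated correlation), and the low Myl7 of ApoeKO_HFD replicates 2 and 3 goes with it. Antigen presentation genes had −0.39 (adjusted p = 1.46e-07; adjusted p = 0.238 with an estimated correlation) and immediate early genes −0.29 (adjusted p = 1.45e-07; adjusted p = 0.326 with an estimated correlation; −0.45 to −0.19 without 1 library). Endothelial markers were higher, with a median of 0.31 (adjusted p = 7.51e-05; adjusted p = 0.723 with an estimated correlation; 0.16 to 0.40 without 1 library). With a covariate of atrial genes the calls on immediate early genes and endothelial markers ended, each at an adjusted p of 0.364. The unfolded protein response had −0.16 (adjusted p = 0.000434; adjusted p = 0.476 with an estimated correlation; 0.444 without ApoeKO_HFD replicate 3). Fatty acid oxidation had −0.10 (adjusted p = 0.0151) and mitochondrially encoded genes 0.15 (adjusted p = 0.0332), each with adjusted p = 0.891 with an estimated correlation. The first of these was lost without ApoeKO_CD replicate 2 (0.23) or 3 (0.776) or ApoeKO_HFD replicate 2 (0.429) or 3 (0.505). The second was lost without ApoeKO_CD replicate 2 (0.217) or 3 (median −0.08) or ApoeKO_HFD replicate 2 (median −0.13), and reached 0.44 without ApoeKO_CD replicate 1. The medians ran from −0.39 to −0.08 for the unfolded protein response and −0.24 to −0.02 for fatty acid oxidation.

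WT_HFD against WT_CD gives the effect of diet under the wild-type label. Atp5k was lower by 2.82-fold (SE 0.22 in log2, adjusted p = 0.00603), at 28.4 ± 0.474 CPM (SD, n = 2) against 80.2 ± 27.0 (n = 3). Lars2, the mitochondrial leucyl-tRNA synthetase, was also lower, with a log2 fold change of −1.74 (SE 0.27, adjusted p = 0.0134). Bcl6, a transcriptional repressor, had −0.93 (SE 0.18), Mir6236 −2.11 (SE 0.27), Ccdc124 −1.08 (SE 0.17), and Ccdc9, near Apoe, −1.19 (SE 0.22). Higher were Gpr22, an orphan receptor, at 0.90 (SE 0.17), Lgals4 at 1.21 (SE 0.22), Bcam at 0.69 (SE 0.14), Tmed7 at 0.91 (SE 0.17) and AC132253.9 at 1.30 (SE 0.20), all with adjusted p of 0.0415 or less. In all 9 genes were higher and 26 lower, and 2176 had an unadjusted p under 0.05 (1016 with only the 2 groups fitted). None of the 35 overlapped between groups, where chance gives 20% and all tested genes 24.7%. The count was 1019 without WT_CD replicate 2, 4 without WT_HFD replicate 1 and 7 without WT_HFD replicate 2. Mir6236 passed in each of the 5 fits that left out 1 library. Lost without either WT_HFD replicate were Atp5k (−1.64 to −1.19), Lars2 (−1.95 to −1.31), Ccdc124 (−1.20 to −0.92) and AC132253.9 (1.11 to 1.62). Lgals4 was lost without these or WT_CD replicate 1 (0.98 to 1.51), as was Bcl6 (nearest 0 at −0.80). Bcam (0.60 to 0.76), Ccdc9 (−1.41 to −0.96), Gpr22 (0.78 to 1.10) and Tmed7 (0.80 to 1.09) passed only without WT_CD replicate 2. Lars2, Mir6236, Atp5k, Bcl6 and Ccdc124 were high and Gpr22, Tmed7 and AC132253.9 low in mean in WT_CD alone. Lars2 had 154, 341 and 178 CPM in WT_CD replicates 1 to 3 and 56.5 to 105 in the others. Gm42418, annotated as a lincRNA and chosen after its values were seen, moved with it, at 2160, 4320 and 2240 CPM in WT_CD and 902 to 1610 in the others. Mir6236 did too, at 208, 395 and 332 CPM in WT_CD and 51.6 to 115 in the others. Each of these was highest in WT_CD replicate 2, and the cause of the joint rise was not tested. Differences of genes that stood apart in WT_CD alone are therefore not shown to be specific to diet.

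The 3 lists that passed camera between these groups did so at an adjusted p of 0.0247, each with adjusted p = 0.98 with an estimated correlation. LXR targets had a median of −0.28, with 11 of 13 below 0, 0 called over all genes and 1 adjusted over the list alone. Scd2 had −0.91 (SE 0.24, adjusted p = 0.168). Hypertrophy and fetal genes had −0.32, with 16 of 21 below 0, and Nppb, the B-type natriuretic peptide gene, had −0.71 (SE 0.28, adjusted p = 0.3). Extracellular matrix genes had 0.26, with 26 of 34 above 0, and Timp2, an inhibitor of matrix proteases, had 0.71 (SE 0.19, adjusted p = 0.172). Without WT_CD replicate 2 no list passed, without its replicate 1 LXR targets did not (0.0823), and without WT_HFD replicate 2 neither LXR targets (0.0587) nor hypertrophy genes (0.545) did. Without 1 library the median of hypertrophy genes was −0.44 to −0.10, that of extracellular matrix genes 0.19 to 0.43, and Nppb −0.92 to −0.46. The number of lists was 5 without WT_CD replicate 1, 10 without WT_HFD replicate 1 and 8 without WT_HFD replicate 2.

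ApoeKO_CD against WT_CD gives the effect of genotype on chow, in the direction of the labels. Each direction below would be reversed if the labels of the chow groups were exchanged. LXR targets were lower as a list. Scd2 had 2.56 ± 0.234 CPM (SD, n = 3) in the libraries labelled ApoeKO_CD and 14.8 ± 4.15 (n = 3) in WT_CD, a fall by 2.52 on the log2 scale (SE 0.23, adjusted p = 4.14e-05). Abca1, the transporter that exports cholesterol to apolipoproteins, fell by 1.29 (SE 0.16, adjusted p = 0.000501), from 66.8 ± 6.20 to 27.4 ± 6.57 CPM. Srebf1 fell by 1.13 (SE 0.19, adjusted p = 0.00859), which was lost without WT_CD replicate 3. Of 13 tested LXR targets 10 lay below 0, with a median of −0.81, 3 called over all genes and 7 adjusted over the list alone. Camera gave an adjusted p of 3.25e-11 (adjusted p = 0.0156 with an estimated correlation), fry gave 0.00312, and the camera call held in each of the 6 fits that left out 1 library, with a median of −0.50 without ApoeKO_CD replicate 3 and −0.95 without WT_CD replicate 2.

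**Figure D4:**
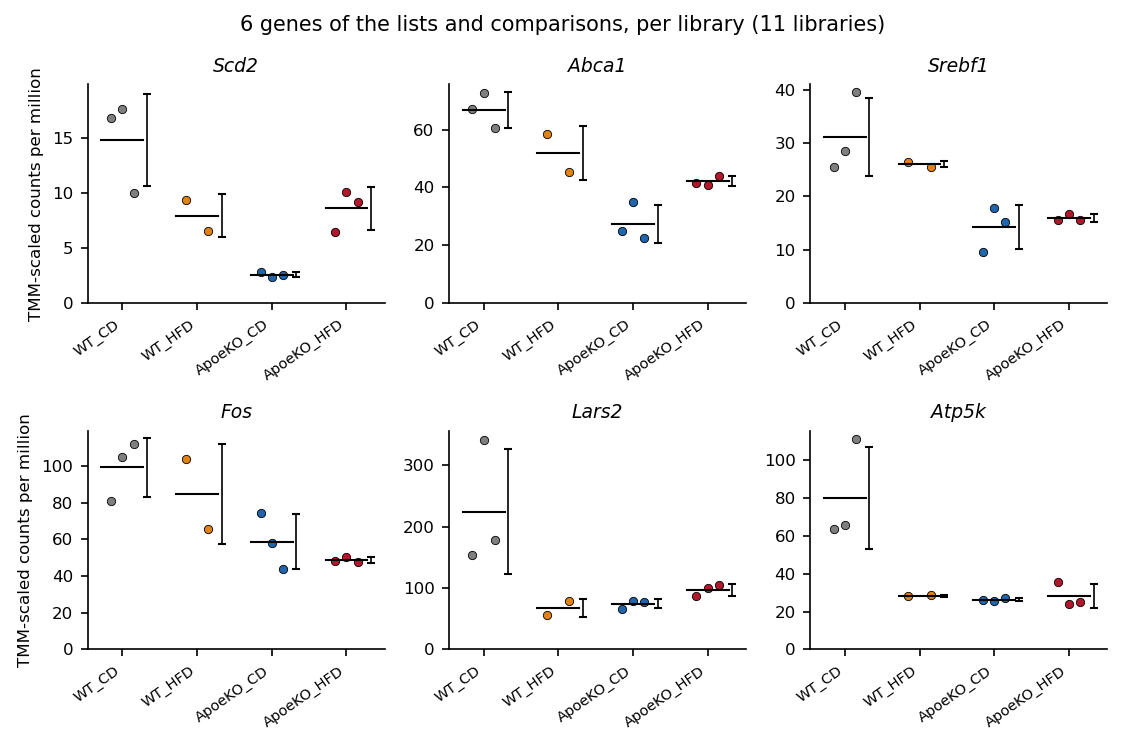
TMM-scaled CPM of 6 genes in each of 11 libraries by labelled group (points, libraries; line, mean; bar, SD). Scd2 is lowest in ApoeKO_CD at 2.56 and highest in WT_CD at 14.8, and Atp5k stands at 80.2 in WT_CD and between 26.2 and 28.4 in the other groups.

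Other genes lower in ApoeKO_CD were Atp5k by −1.61 (SE 0.19, adjusted p = 0.000465), Lars2 by −1.60 (SE 0.24), Mir6236 by −2.01 (SE 0.23), Gadd45g by −1.09 (SE 0.23), Ccdc9 by −1.12 (SE 0.20) and Romo1, a mitochondrial inner membrane protein, by −0.99 (SE 0.22). Ndufa1, a subunit of complex I, had −0.89 (SE 0.19), and Atp5o −0.82 (SE 0.18), which is uncertain because a second annotated gene overlaps it on the same strand. Higher were Iigp1, an interferon-induced GTPase, at 1.28 (SE 0.25, adjusted p = 0.0323), Cenpf, a kinetochore protein, at 0.91 (SE 0.18), the interleukin 13 receptor gene Il13ra1 at 0.78 (SE 0.16), AC132253.9 at 1.11 (SE 0.18), Tmed7 at 0.84 (SE 0.16), Bcam at 0.73 (SE 0.12) and Tmem170b at 0.63 (SE 0.13). In all 21 genes were higher and 65 lower, and 2686 had an unadjusted p under 0.05 (1687 with only the 2 groups fitted). None of the 86 overlapped between groups, against 10% by chance and 16.6% of tested genes. The count was 1801 without WT_CD replicate 2, 42 without WT_CD replicate 3, and 52, 44 and 37 without ApoeKO_CD replicates 1, 2 and 3. Scd2, Abca1, Atp5k, Lars2, Mir6236 and AC132253.9 passed in each of the 6 fits that left out 1 library. Iigp1 was lost without WT_CD replicate 1 or 3 or ApoeKO_CD replicate 2 (0.88 to 1.48), Bcam without ApoeKO_CD replicate 2 (0.64 to 0.80), and Il13ra1 without that, WT_CD replicate 3 or ApoeKO_CD replicate 3 (0.71 to 0.91). Cenpf (0.73 to 1.10) and Gadd45g (−1.42 to −0.80) were lost without WT_CD replicate 1 or 3 or ApoeKO_CD replicate 1 or 2, Tmed7 (0.73 to 1.02) without WT_CD replicate 1 or 3 or ApoeKO_CD replicate 2 or 3, and Tmem170b passed only without WT_CD replicate 2 (0.58 to 0.68). Lost were also Ccdc9 (−1.34 to −0.93), Romo1 (−1.16 to −0.80), Ndufa1 (−1.05 to −0.71) and Atp5o (−1.04 to −0.68) without WT_CD replicate 3 or any 1 of the ApoeKO_CD replicates. Atp5k, Lars2, Mir6236, Romo1, Ndufa1 and Atp5o were high and Iigp1, Cenpf, Il13ra1, AC132253.9, Tmed7 and Tmem170b low in mean in WT_CD alone, so these are not shown to be specific to genotype.

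PPAR-alpha targets, endothelial markers and immediate early genes were also lower in ApoeKO_CD. PPAR-alpha targets had a median of −0.42, with 1 called over all genes and 8 adjusted over the list alone (camera adjusted p = 1.06e-06; adjusted p = 0.779 with an estimated correlation). The called member, Mgll, which encodes monoglyceride lipase, had −0.89 (SE 0.16, adjusted p = 0.0107), and was lost without WT_CD replicate 3, ApoeKO_CD replicate 1 or ApoeKO_CD replicate 3 (−0.97 to −0.81). Endothelial markers had −0.60, with 21 of 22 below 0, 2 called over all genes and 5 adjusted over the list alone (adjusted p = 1.23e-06; adjusted p = 0.935 with an estimated correlation). Gpihbp1, which carries lipoprotein lipase to the capillary lumen, had −1.53 (SE 0.28, adjusted p = 0.015) and Ly6e −1.11 (SE 0.23, adjusted p = 0.0338). Gpihbp1 was lost without WT_CD replicate 1 or 3 or ApoeKO_CD replicate 2 or 3 (−1.83 to −1.32), and Ly6e passed only without WT_CD replicate 2 (−1.34 to −0.90). Immediate early genes had −0.38, with 0 called over all genes and 6 adjusted over the list alone (adjusted p = 4.31e-06; adjusted p = 0.819 with an estimated correlation). The unfolded protein response was higher at 0.26 (adjusted p = 0.015), and mitochondrially encoded genes at −0.27 (adjusted p = 0.0185) and interferon-stimulated genes at −0.42 (adjusted p = 0.0289) were lower, each with adjusted p = 0.955 with an estimated correlation. The call on the unfolded protein response was lost without WT_CD replicate 3 (0.109) or ApoeKO_CD replicate 1 (0.0735) or 2 (0.0572). That on mitochondrially encoded genes was lost without WT_CD replicate 3 (0.154) or ApoeKO_CD replicate 2 (0.0572) or 3 (0.328), and that on interferon-stimulated genes without WT_CD replicate 1 (0.159) or 3 (0.109) or ApoeKO_CD replicate 3 (0.464). Their medians ran from 0.14 to 0.37, −0.57 to −0.08 and −0.67 to −0.16 without 1 library. The number of lists was 4 without WT_CD replicate 3.

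ApoeKO_HFD against WT_HFD gives the effect of genotype on the high fat diet. Lgals4 fell by 2.46 on the log2 scale (SE 0.23, adjusted p = 7.18e-05), from 36.6 ± 0.875 CPM (SD, n = 2) to 6.65 ± 0.391 (n = 3). Actg1, a cytoskeletal actin, fell by 0.76 (SE 0.13, adjusted p = 0.0485). In all 5 genes were higher and 3 lower, 5 of the 8 lay near Apoe, and 480 had an unadjusted p under 0.05 where chance gives 847 (966 with only the 2 groups fitted). None of the 8 overlapped between groups, where chance gives 20%. The count was 4 without WT_HFD replicate 1 and 5 without any 1 of the ApoeKO_HFD replicates. Lgals4 passed in each of the 5 fits that left out 1 library and Actg1 in 0 (−0.84 to −0.69).

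Immediate early genes, PPAR-alpha targets and endothelial markers were lower as lists between these groups. Of 23 immediate early genes 23 lay below 0, with a median of −0.61, 0 called over all genes and 15 adjusted over the list alone. Camera gave an adjusted p of 1.04e-29 (adjusted p = 0.0678 with an estimated correlation), with Zfp36, an mRNA decay factor, at −0.92 (SE 0.23, adjusted p = 0.517) and Fos at −0.80 (SE 0.21, adjusted p = 0.597). Without 1 library these ran from −1.23 to −0.54 and −1.10 to −0.44. PPAR-alpha targets had −0.36, with 1 called over all genes and 4 adjusted over the list alone (adjusted p = 5.2e-13; adjusted p = 0.214 with an estimated correlation; median −0.17 without WT_HFD replicate 2). Endothelial markers had −0.39, with 22 of 22 below 0 (adjusted p = 5.06e-09; adjusted p = 0.477 with an estimated correlation). Their median was −0.61 without WT_HFD replicate 1 and −0.14 without WT_HFD replicate 2. Extracellular matrix genes had −0.30 (adjusted p = 1.43e-07; adjusted p = 0.421 with an estimated correlation). Fatty acid oxidation enzymes had −0.23 (adjusted p = 8.68e-07; adjusted p = 0.66 with an estimated correlation; 0.115 without WT_HFD replicate 2; median −0.40 to −0.09). Antigen presentation genes had −0.32 (adjusted p = 2.1e-05; adjusted p = 0.398 with an estimated correlation; median −0.20 without WT_HFD replicate 1).

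Further list differences between these groups turned or lost their call when 1 library was left out. Atrial genes had −1.19 (adjusted p = 0.00313; adjusted p = 0.66 with an estimated correlation), and without WT_HFD replicate 1 their median was 2.39; the other WT_HFD library had 0.0668 CPM of Myl7. Cell cycle genes had −0.17 (adjusted p = 0.00393; adjusted p = 0.477 with an estimated correlation), which was lost without WT_HFD replicate 2 (0.081) or ApoeKO_HFD replicate 1 (0.208). Pericyte and smooth muscle markers had −0.34 (adjusted p = 0.035; adjusted p = 0.665 with an estimated correlation), lost without WT_HFD replicate 2 (0.305) or ApoeKO_HFD replicate 2 (0.161). Glycolysis had 0.08 and NF-kappaB and cytokine genes −0.28, both at an adjusted p of 0.0457 (adjusted p = 0.807 with an estimated correlation). The former was lost without WT_HFD replicate 1 (0.787) or ApoeKO_HFD replicate 1 (0.97). The latter was lost without ApoeKO_HFD replicate 1 (0.0777) or 2 (0.151) and had a median of 0.28 without WT_HFD replicate 1. Without 1 library the medians were −0.35 to −0.05 for cell cycle genes, −0.47 to −0.12 for pericyte markers and −0.05 to 0.16 for glycolysis. The number of lists was 18 without ApoeKO_HFD replicate 3.

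The interaction asks whether diet acted differently under the 2 genotype labels. It answers that only if the labels of the chow groups hold. With them exchanged it would be the sum of the genotype effects on the 2 diets. Scd2 had an interaction of 2.64 on the log2 scale (SE 0.34, adjusted p = 0.000648): its diet effect was −0.91 between the libraries labelled WT and 1.73 between those labelled ApoeKO. Outside the region of Apoe, positive interactions were also found for Mir6236 at 2.50 (SE 0.35), Lars2 at 2.12 (SE 0.36), Zkscan3 at 1.72 (SE 0.25), Atp5k at 1.61 (SE 0.29) and Ccdc124 at 1.19 (SE 0.22), and a negative one for AC132253.9 at −1.48 (SE 0.27). Mir6236, Lars2, Atp5k and Ccdc124 were high and AC132253.9 low in the WT_CD libraries alone, with Atp5k at 80.2 CPM there and 26.2 to 28.4 in the other groups. Near Apoe stood Lgals4 at −3.00 (SE 0.31), Bcam at −1.38 (SE 0.19) and Ccdc9 at 1.73 (SE 0.30). LXR targets had a median of 0.64, with 12 of 13 above 0, 1 called over all genes and 6 adjusted over the list alone (camera adjusted p = 1.41e-07; adjusted p = 0.0556 with an estimated correlation; fry 0.0367). Extracellular matrix genes had −0.38, with 28 of 34 below 0 (adjusted p = 0.0153; adjusted p = 0.933 with an estimated correlation), a call that ended without WT_CD replicate 2 (0.252), ApoeKO_CD replicate 1 (0.106) or ApoeKO_HFD replicate 2 (0.0741), with medians of −0.64 to −0.14. In all 29 genes had a positive and 8 a negative interaction, 13 genes other than Apoe near it, and 1389 had an unadjusted p under 0.05. The count was 285 without WT_CD replicate 2, 20 without WT_HFD replicate 1, and 23 and 22 without ApoeKO_HFD replicates 2 and 3. Scd2, Mir6236, Zkscan3, Lgals4 and Bcam passed in each of the 11 fits that left out 1 library, Lars2 and Ccdc9 in 8, Atp5k in 7, Ccdc124 in 5 and AC132253.9 in 4.

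No gene was called in the same direction by diet under both genotype labels, or by genotype on both diets. Diet called 7 genes in opposite directions: Pnmal2, Trappc6a, Igsf23, Blvrb and Zfp30 were higher on the high fat diet in ApoeKO and lower in WT, and Bcam and Lgals4 were the reverse. Independent lists would share 0.0138 genes of the first kind (Fisher's exact test, p = 7.12e-13). Genotype called 5 genes in opposite directions on the 2 diets, Pnmal2, Ccdc8, Igsf23, Blvrb and Zfp30, where independent lists would share 0.0192 (Fisher's exact test, p = 7.13e-13). Those of these genes not named above were chosen after their values were seen. All lie within 10 Mb of Apoe except Zfp30, which lies just outside, at 29783998 to 29794702 on chromosome 7. The exact test takes such neighbours as independent, so these p-values overstate the evidence. With the labels of the chow groups exchanged, same and opposite directions of the genotype effect would trade places. The diet comparisons would then mix diet with genotype. Over 4949 genes with a mean log2 CPM of at least 3, the diet effects under the 2 labels correlated at −0.27 (Pearson) and −0.22 (Spearman), and the genotype effects on the 2 diets at −0.03 and −0.05, across genes, which are not independent replicates. By DESeq2 the genotype effect had 3 genes in the same direction: 1 higher on both diets (expected 0.16, Fisher's exact test, p = 0.149) and 2 lower (expected 0.198, p = 0.0163). By edgeR at an unadjusted p under 0.01 it had 2 higher (expected 1.11, exact p = 0.305) and 12 lower on both diets, among them Fos, Atf3, Srebf1 and Acot1 (expected 1.75, exact p = 1.34e-07). The diet effect had 0 in the same direction by both.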

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

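The tests in this part were chosen after the results were seen, except the splits of libraries and the odds ratios of 10.5 and 117 near Apoe, whose predictions were written before the calls were seen. Groups of 3 libraries were not tested for outliers.

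The counts of WT_HFD replicate 3 stood out as a signal in a library that no comparison uses. On opposite-strand gene pairs 60.823% of its counts were on the non-coding member, against at most 0.259% in the 11 other libraries, which is what counting on the opposite strand predicts. Reads from genomic DNA would follow exon length, of which the non-coding members hold 7.18%, and so do not account for it. The header of the file names ApoeKO_CD replicate 1, but the correlation of its deviations with that library exceeded that with the next library by only 0.014, so whose reads these are stays open. No biological explanation was tested for this library.

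Apoe and genes near it stood out because the diet effect differed between the genotype labels: the interaction was −5.03 for Apoe, −3.00 for Lgals4, −1.38 for Bcam and 1.73 for Ccdc9. Exchanged genotype labels of the 2 chow groups would make the 2 genotype comparisons run opposite to each other near Apoe, but the correlation of −0.52 there restates the observation and is no test of an exchange. The odds ratios of 10.5 on chow and 117 on the high fat diet are as predicted for sequence of the donor strain around the knockout allele. An exchange of labels would carry that sequence along. With the labels as they stand, such sequence alone would shift genes in the same direction on both diets. The correlation of −0.52 near Apoe, against −0.06 elsewhere, argues against that for the region. If RNA from macrophages carried Apoe, a median interaction of −2.52 or lower was predicted for their markers. It was −0.82 (SE 0.23, 20 markers). Markers are not independent and the bar was set after the values were seen, so this shows only a smaller shift than that of Apoe. In ApoeKO_CD replicates 1 to 3 the macrophage gene Lyz2 had 8.94, 8.59 and 1.14 CPM and Apoe 25.2, 23.9 and 6.93, so macrophage RNA may contribute. In WT_CD Lyz2 had 4.55, 2.59 and 1.5 CPM and Apoe 2.91, 2.12 and 3.61. In WT_HFD replicates 1 and 2 Lyz2 had 5.92 and 0.802 CPM and Apoe 18.9 and 8.44. An interaction unrelated to position would not give the odds ratio of 40.9. A response to diet tied to this locus was not tested directly. Under the labels it would have to bring ApoeKO_HFD to WT_CD levels across the region. Of 243 genes near Apoe, 1 was called in ApoeKO_HFD against WT_CD, Lgals4 (Fisher's exact test, odds ratio 2.75, interval 0.0668 to 17.0, p = 0.313). By the same test WT_HFD against WT_CD had 9 (odds ratio 24.6) and ApoeKO_HFD against ApoeKO_CD 8 (odds ratio 142). Apart from Lgals4, such a response and an exchange of labels both predict these counts, which therefore cannot tell them apart. An exchange of labels may be the cause but is not shown to be, and the labels were kept.

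The WT_CD libraries stood apart from the other groups, which was noticed in the comparisons and not by a rule. They also stood far from each other. On the first principal component of tested nuclear genes (25.5% of variance) WT_CD replicates 1 to 3 had −27.21, 12.19 and −95.02. The other libraries had 7.32 to 21.01. On the second (17.8%) WT_CD had −41.39, 72.99 and 16.72, and the other libraries −18.24 to 5.98. Scatter within the group is therefore part of the difference. Fewer genes were detected in WT_CD replicates 2 and 3, with 26550 and 25968 at an equal depth of 9340449 nuclear counts. The highest WT_CD library had 30631, above the lowest other library at 29570, so lower library complexity could contribute but does not separate the group. Gene length had a Spearman rho of 0.155 with the log2 fold change of ApoeKO_CD against WT_CD, and the genes called lower there had a median exon length of 1831 bases against 4715 for tested genes (1724 in ApoeKO_HFD and 1696 in WT_HFD against WT_CD), so a length bias may contribute and stays open. A biological cause in the wild-type chow group was not separated from these. Lars2, Mir6236 and Gm42418 were each highest in WT_CD replicate 2, at 341, 395 and 4320 CPM, and the cause of that joint rise was not tested.

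Real and exchanged groupings of the libraries were compared by the number of called genes, with 10 splits for each pair of groups. The real split was the only 1 to reach its count for ApoeKO_HFD against WT_CD (26, others at most 1), ApoeKO_HFD against ApoeKO_CD (12, others at most 1), ApoeKO_CD against WT_CD (86, others at most 3) and ApoeKO_HFD against WT_HFD (8, others at most 1), and 10 splits are too few for a share under 0.05. For WT_HFD against WT_CD 2 splits reached 35 genes, the other with 1146. For the interaction 10 of 100 splits reached its 37 genes, with up to 538, so chance is not excluded for that number.

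Further differences in the diet effect between the genotype labels follow, which are such only if the labels of the chow groups hold. The interaction was 2.64 for Scd2, 2.50 for Mir6236, 2.12 for Lars2, 1.72 for Zkscan3 and 1.61 for Atp5k. It was 1.19 for Ccdc124 and −1.48 for AC132253.9. Of these, Mir6236, Lars2, Atp5k and Ccdc124 were high and AC132253.9 low in the 3 WT_CD libraries alone, with Atp5k at 80.2 CPM there and 26.2 to 28.4 in the other groups. By DESeq2 Zkscan3, outside the region of Apoe, was called lower for genotype on chow and higher on the high fat diet, as Igsf23 was. As lists, LXR targets differed at a camera adjusted p of 1.41e-07 (adjusted p = 0.0556 with an estimated correlation) and extracellular matrix genes at 0.0153 (adjusted p = 0.933 with an estimated correlation).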

How the results depend on the processing

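The counts of called genes depend on the processing more than the directions of named genes and list medians do. Apart from Apoe, those genes were named by their values in the same libraries, so a kept direction is no independent support. Counts follow in the order ApoeKO_HFD against WT_CD, ApoeKO_HFD against ApoeKO_CD, WT_HFD against WT_CD, ApoeKO_CD against WT_CD, ApoeKO_HFD against WT_HFD, and the interaction, where the reported ones are 26, 12, 35, 86, 8 and 37. The fit of all 12 libraries, which the design fixed beforehand, gave 0, 1, 1, 3, 1 and 8 by edgeR, with 576 genes at an unadjusted p under 0.05 in the first. No filter gave 296, 26, 272, 475, 49 and 105, and DESeq2 204, 20, 168, 434, 28 and 92. The 2 groups alone gave 12, 16, 9, 38 and 24, a fit that does not exist for the interaction, and voom with sample weights gave 33, 23, 45, 69, 39 and 72. The replicate number as a block, where the libraries share only a number, gave 14, 9, 19, 61, 7 and 27. A covariate of clock genes gave 30, 10, 11, 57, 5 and 26, one of atrial genes 1, 9, 22, 67, 6 and 33, and one of non-myocyte markers 36, 13, 38, 153, 11 and 35. The covariates of clock and atrial genes were added after seeing the data, as was the removal of mitochondrial genes. RLE factors, a filter of 50 counts and that removal kept each count within 1.5 times. Without 1 library the counts ran from 0 to 1304, 6 to 8, 4 to 1019, 37 to 1801, 4 to 8, and 20 to 285. The fit without WT_HFD replicate 3 is the reported one, and where WT_HFD is left with 1 library, that library is assumed to vary like the other groups.

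The lists passing camera were 10, 10, 3, 7, 11 and 2 in the same order. With an estimated correlation they were 0, 1, 0, 1, 0 and 0, and with fry 0, 0, 0, 1, 0 and 1. All 12 libraries gave 12 for WT_HFD against WT_CD and 13 for the interaction. The covariate of atrial genes gave 6 for ApoeKO_HFD against ApoeKO_CD and 5 for WT_HFD against WT_CD. For the interaction the filter of 50 counts gave 1 and the covariate of non-myocyte markers 5. The latter gave 15 for ApoeKO_HFD against ApoeKO_CD and 2 for WT_HFD against WT_CD. Without 1 library the lists were 7 to 10, 9 to 18, 0 to 10, 4 to 9, 10 to 18, and 2 to 13. Genes sharing the direction of the genotype effect on both diets were 3 by DESeq2 and 14 at an unadjusted p under 0.01.

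Among values of named genes 2669 kept direction and side of the threshold, 410 kept the direction only and lost the call, 111 gained one, and 7 turned. Among list medians 494 kept both, 93 lost the call and 8 turned. For ApoeKO_HFD against WT_CD, Apoe turned to 0.27 with the covariate of atrial genes, 0.08 without WT_CD replicate 3 and 0.10 without ApoeKO_HFD replicate 1, and Pf4 to 0.12 with that covariate; Apoe was lowest at −0.27 without WT_CD replicate 2. In ApoeKO_HFD against ApoeKO_CD mt-Atp6 turned to −0.08 without ApoeKO_HFD replicate 2 and was highest at 1.62 without its replicate 1. In ApoeKO_HFD against WT_HFD Decr1 turned to 0.01 with all 12 libraries and Bmp10 to 1.68 without WT_HFD replicate 1, against −5.43 without replicate 2. Among medians, oxidative phosphorylation genes turned to 0.19 without WT_CD replicate 2 and were lowest at −0.26 without ApoeKO_HFD replicate 1 (ApoeKO_HFD against WT_CD), and mitochondrially encoded genes to −0.08 without ApoeKO_CD replicate 3 and −0.13 without ApoeKO_HFD replicate 2, with 0.44 without ApoeKO_CD replicate 1 (ApoeKO_HFD against ApoeKO_CD). In ApoeKO_HFD against WT_HFD, fatty acid oxidation enzymes turned to 0.15 with all 12 libraries, NF-kappaB and cytokine genes to 0.09 with the covariate of non-myocyte markers and 0.28 without WT_HFD replicate 1, and atrial genes to 0.30 with their own covariate and 2.39 without WT_HFD replicate 1. Without WT_HFD replicate 2 these 2 medians were −0.65 and −2.21. Except for the atrial genes under their own covariate and fits with fewer libraries, the cause was not tested. Depth is lowest in WT_HFD replicate 3, with 1347110 counts, and the lowest other library had 9340449 nuclear counts.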

Other observations

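The test of atrial cells in this part was chosen after the result was seen, and so were the genes named for single libraries. The lower hypertrophy and fetal genes of ApoeKO_HFD against ApoeKO_CD raised the hypothesis that fewer atrial cells account for them. Without Nppa, Myl4 and Myl7 the list still had a camera p of 2.85e-08 at the preset correlation, where atrial cells alone predicted no pass. In ApoeKO_HFD against WT_CD it had 0.0779 without these genes. In the former comparison the whole list had an adjusted p of 0.238 with an estimated correlation, so this test does not settle the question.

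Single libraries differed within groups. Dbp, a clock output gene, had 42.5 CPM in WT_HFD replicate 1, 37.4 in ApoeKO_CD replicate 2 and 18.0 in ApoeKO_HFD replicate 1, and 1.45 to 8.64 in the 8 others. Lyz2, a macrophage gene, had 8.94, 8.59 and 1.14 CPM in ApoeKO_CD replicates 1 to 3. Myl4, an atrial light chain, had 0.646 CPM in WT_HFD replicate 2 and 1.72 and 2.28 in ApoeKO_HFD replicates 2 and 3, against 13.2 to 50.2 in the others. Gm42418, annotated as a lincRNA, had 2160, 4320 and 2240 CPM in WT_CD replicates 1 to 3 and 902 to 1610 in the others.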
